A study of Homo sapiens with 9 samples.

How the data were processed

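Total RNA was profiled by sequencing in 9 libraries from H1299, an established human non-small cell lung carcinoma line. Per the labels, cells were kept in serum free medium as the control, treated with siCLOCK (small interfering RNA against CLOCK) or treated with 0.1 mM melatonin, with 3 independent samples per group. The labels describe no non-targeting siRNA control, no treatment time and no library or sequencing date, and they do not say whether the 3 samples of a group were separate cultures. Paired-end reads came from a BGIseq500 instrument.

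The deposited files hold raw counts per gene, made by the authors with STAR 2.7.9a on the human genome build GRCh38 (hg38). Each file gives counts for 58721 genes regardless of strand and for each strand, after summary lines for unmapped, multimapping, no-feature and ambiguous reads. All 58721 gene identifiers matched GENCODE release 29, which supplied symbols, gene types and coordinates. That release was inferred from the identifiers and is not stated by the authors. The ratio of the strand totals lay between 1.01 and 1.05, so the libraries were not stranded and the counts regardless of strand were used. Reads from overlapping or antisense genes, and from near-identical gene copies, cannot be separated in such counts.

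Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr over the 3 groups, which left 16441 genes. Libraries were scaled with TMM, and 1 quasi-likelihood model with a term per group was fitted to all 9 libraries, with a biological coefficient of variation of 0.0682. Tests were two-sided F tests, adjusted over all genes tested by the Benjamini-Hochberg method, and a gene passed at an adjusted p under 0.05. Levels are TMM-scaled CPM, given as mean and SD over 3 libraries. The standard error (SE) of a log2 fold change is its size divided by the square root of F. These p-values measure only the spread between these samples. For CLOCK a two-sided exact permutation test on CPM was also run, in which 3 against 3 libraries cannot give a p below 0.1. Intervals of shares of reads are 95% Wilson intervals and cover counting error only.

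Before the data were examined, 35 gene lists with 618 symbols were fixed from general knowledge. They cover clock repressors and outputs, clock activators and regulators, clock-linked metabolic outputs, melatonin receptors, synthesis and metabolism, AhR targets, DNA replication and G1/S, G2/M and mitosis, interferon-stimulated genes, NF-kB targets, the unfolded protein response, ATF4 targets and amino acid supply, hypoxia and glycolysis, epithelial-mesenchymal transition, matrix and matrix remodelling, TGF-beta targets, YAP/TEAD targets, immediate early genes, cholesterol synthesis and uptake, fatty acid synthesis, p53-linked targets, NRF2 and antioxidant genes, apoptosis regulators, autophagy and lysosome, antigen presentation, mitochondrially encoded genes, the nuclear-encoded respiratory chain, ribosomal proteins, replication-dependent histones, heat shock and abundant non-coding RNAs. Leukocyte, erythroid, fibroblast, endothelial and lung epithelial markers stood for other cells. The 31 lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over these lists. Beside each list call stands the adjusted p with an estimated correlation. Members were counted at the adjustment over all genes and also adjusted over the list alone.

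Also fixed before the data were examined was the choice of named genes. These were the 10 protein-coding genes with the largest rise and the 10 with the largest fall per treatment (5 and 5 for melatonin against siCLOCK), among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups' libraries. CLOCK, members of the clock lists and 2 to 4 members with the smallest p of each other list were named as well. For the overlap of the treatments, up to 5 genes per direction were named. Genes named outside these choices are said to be so where they appear.

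Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a filter of 5 CPM in at least 3 libraries, only the 6 libraries compared, a replicate block, protein-coding genes only, a strand-specific count column, each library left out in turn, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and for lists fry and the estimated correlation. After the data were seen, a term for 2 technical sets of libraries was added, divided at 1.8% unmapped reads, as was the comparison of melatonin with control without the library labelled siCLOCK replicate 3. The covariance of the 2 treatments' fold changes was set beside 20 simulations in which neither treatment had an effect and all libraries varied around 1 mean. On simulated data with 16441 genes, the procedure called 70% of genes changed 1.5-fold and 83% of genes changed 2-fold, and 8 of 171 calls were unchanged genes. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.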

Results

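The series compared gene expression in H1299 lung carcinoma cells kept in serum free medium (control), given siRNA against the circadian transcription factor CLOCK (siCLOCK), or given 0.1 mM melatonin, the pineal hormone that signals darkness. The title of the series places both treatments in the setting of circadian rhythm dysfunction. Each group had 3 libraries. Counts assigned to genes ranged from 15384539 in melatonin replicate 1 to 19192962 in siCLOCK replicate 2. In a principal component analysis, the first component took 40.8% of the variance. It placed the controls between -18.8 and -16.2, siCLOCK replicates 1 and 2 at -19.3 and -13.5, the library labelled siCLOCK replicate 3 at 3.93, and the melatonin libraries between 25.9 and 28.2.

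The 9 libraries fell into 2 technical sets that did not follow the groups. In the first set, the 3 controls and siCLOCK replicates 1 and 2, unmapped reads made up 1.22% to 1.36% of reads and processed pseudogenes, intronless copies of other genes, took 0.204% to 0.218% of gene counts. In the second set, the library labelled siCLOCK replicate 3 and the 3 melatonin libraries, these shares were 2.24% to 2.34% and 0.364% to 0.378%. For the library labelled siCLOCK replicate 3 the pseudogene share of 0.364% had a 95% Wilson interval of 0.362% to 0.367%. No control library was in the second set and no melatonin library in the first, so the set and melatonin are separable only through the library labelled siCLOCK replicate 3. A set term is thus estimated only from that library against siCLOCK replicates 1 and 2, and it takes in any other difference between them. With it, melatonin against control takes in how siCLOCK replicates 1 and 2 differed from control. EEF1A1P5, a processed pseudogene of the elongation factor gene EEF1A1 chosen after its values were seen, stood at 158 CPM ± 8.60 (SD, n = 3) in control, 618 CPM in the library labelled siCLOCK replicate 3 and 601 CPM ± 26.8 in melatonin. With the set as a term in the model, added after the data were seen, 125 genes were higher and 34 lower in the second set than in the first, and 96 of the higher genes were processed pseudogenes.

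**Figure D1:**
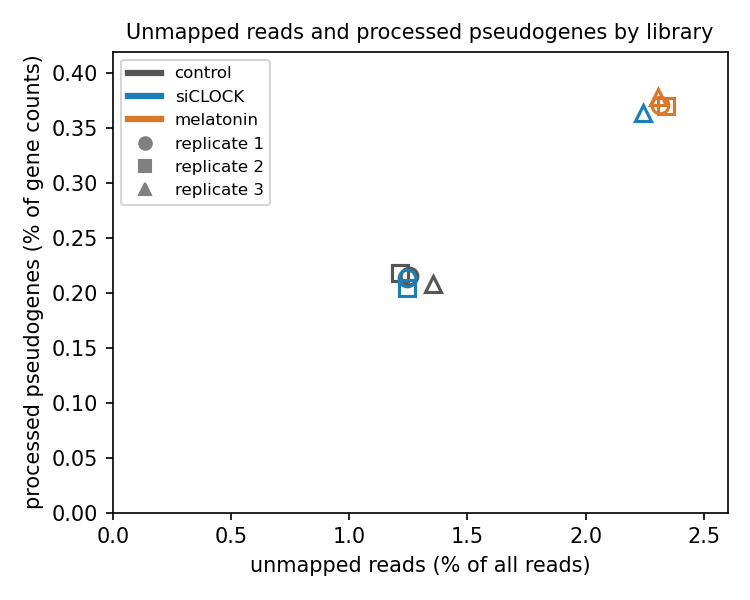
Share of unmapped reads (x axis, % of all reads) against the share of gene counts in processed pseudogenes (y axis, %), with 1 open symbol per library, colour for the group and shape for the replicate. The library labelled siCLOCK replicate 3 (2.24%, 0.364%) lies beside the 3 melatonin libraries, and the other 5 libraries lie at or under 1.36% and 0.218%.

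The first question was whether the siRNA lowered its target. CLOCK (ENSG00000134852.14, chromosome 4, 55427903 to 55547138 on GRCh38), which pairs with ARNTL to drive the circadian feedback loop, averaged 40.7 CPM ± 3.26 (SD, n = 3) in control and 30.4 CPM ± 8.72 in siCLOCK, or 74.7% of control. The siCLOCK libraries were uneven. Relative to the control mean, CLOCK stood at 51.5% in replicate 1 and 78.7% in replicate 2, but at 93.8% in the library labelled siCLOCK replicate 3, so that library does not show the reduction its label implies. The log2 fold change of -0.42 (SE 0.14) did not pass (adjusted p = 0.341), and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. Without the library labelled siCLOCK replicate 3 the log2 fold change was -0.62 (adjusted p = 0.0186), and without siCLOCK replicate 1 it was -0.21 (adjusted p = 0.333). In melatonin, CLOCK averaged 40.5 CPM ± 1.34, a log2 fold change of -0.01 (adjusted p = 0.984, exact permutation p = 0.9). A term for the technical set gave -0.53 (adjusted p = 0.104), but that term rests on the library labelled siCLOCK replicate 3, whose CLOCK level lacks most of the reduction of replicates 1 and 2, so this value is no measure of melatonin.

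Other clock genes did not pass in siCLOCK against control. None of 12 measured clock repressors and outputs passed over all genes, and 2 were higher and 3 lower when adjusted over the list alone. NR1D2, a heme-binding nuclear receptor that represses ARNTL, averaged 33.0 CPM ± 2.03 (SD, n = 3) in control and 23.1 CPM ± 9.34 in siCLOCK, with 12.8, 25.7 and 30.9 CPM in the 3 siCLOCK libraries (log2 fold change -0.51, SE 0.18, adjusted p = 0.393). PER3, a period protein gene, had a log2 fold change of -0.26 (adjusted p = 0.393) and CRY1, a cryptochrome repressor, of 0.19 (adjusted p = 0.781), the latter with 52.6 CPM in siCLOCK replicate 1 and 32.9 and 31.7 CPM in the other libraries. Without siCLOCK replicate 1 the CRY1 value was -0.08. Among 14 measured clock activators and regulators none passed and 1 was higher when adjusted over the list alone: NPAS2, a CLOCK paralog, at 0.38 (SE 0.08, adjusted p = 0.0747), while ARNTL was at 0.12 (adjusted p = 0.760). None of 9 clock-linked metabolic outputs passed. The lists as wholes did not pass either (adjusted p = 0.0858 for repressors, 0.548 for activators and 0.882 for metabolic outputs). Without the library labelled siCLOCK replicate 3, NR1D2 passed at -0.78 (adjusted p = 0.0217) and NPAS2 at 0.41 (adjusted p = 0.0324), and without siCLOCK replicate 1 NPAS2 passed at 0.40 (adjusted p = 0.0438).

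**Figure D2:**
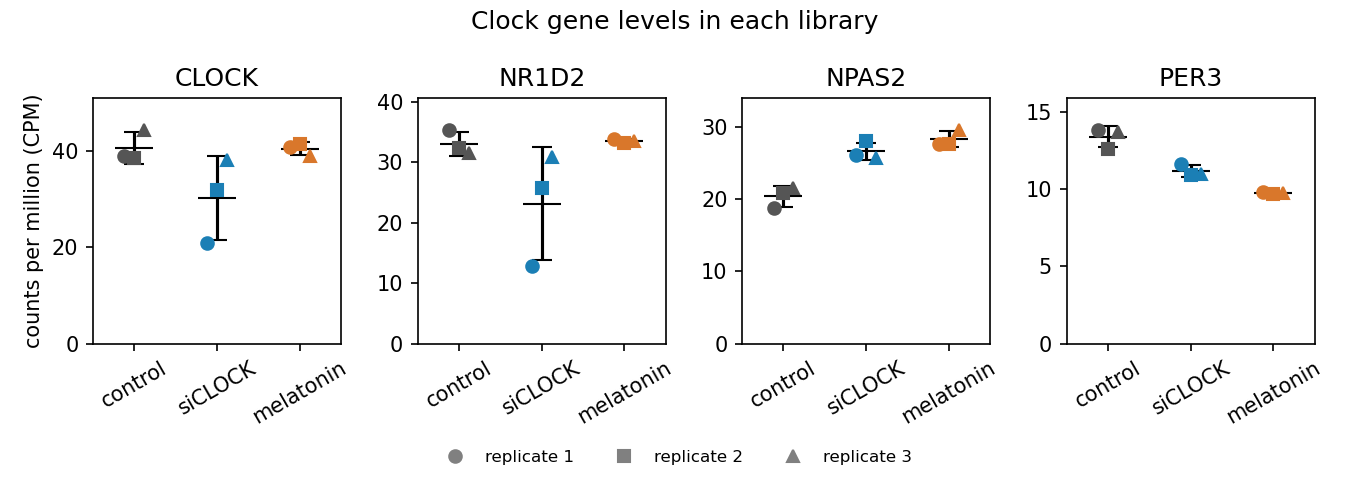
CPM of CLOCK, NR1D2, NPAS2 and PER3 (y axes) in each library by group (x axis); symbols mark replicates, horizontal lines the means and bars 1 SD over 3 libraries. CLOCK ranges from 20.9 to 38.1 CPM across siCLOCK libraries, against 38.6 to 44.4 CPM in control.

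In siCLOCK against control, genes of amino acid supply and of the ATF4 stress response were lower, and 9 single genes were higher. The largest falls among named genes were in CHAC1, a glutathione-degrading enzyme and ATF4 target, from 18.8 CPM ± 2.95 to 8.52 ± 2.83 (SD, n = 3; log2 fold change -1.14, SE 0.18, adjusted p = 0.0164), and SLC7A11 (ENSG00000151012.13, chromosome 4, 138164097 to 138242349), the cystine transporter, from 20.1 CPM ± 2.40 to 10.5 ± 1.34 (-0.94, SE 0.12, adjusted p = 0.00196). ADM2 (-0.69), TRIB3 (-0.62), GADD45B (-0.58) and SESN2 (-0.49) also fell, as did PHGDH (-0.47) and PSAT1 (-0.46) of serine synthesis and MTHFD2 (-0.34) of mitochondrial folate metabolism. ITGA10 (ENSG00000143127.12, chromosome 1, 145891208 to 145910189), a collagen-binding integrin subunit, rose from 46.8 CPM ± 2.23 to 71.5 ± 5.32 (0.61, SE 0.07, adjusted p = 0.00119). SERPINE2, a secreted protease inhibitor, rose by 0.45, the TGF-beta receptor TGFBR2 by 0.43, the cytokine LIF by 0.40 and the phosphate transporter SLC20A1 by 0.39. HAS3, a hyaluronan synthase, was called at 0.63, but its value was -0.01 in a strand-specific count. The cause of that difference was not tested.

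In all, 9 genes were higher and 11 lower of 16441 tested in siCLOCK (1355 at an unadjusted p under 0.05). Other called genes included SH3TC2-DT and FAM3C, higher, and ASNSP1 and NXPH4, lower. Calls rested on few libraries: without control replicate 1, or without siCLOCK replicate 2, only ITGA10 (1 higher) and SLC7A11 (1 lower) passed, and without control replicate 2, 3 genes were higher and 1 lower. Calls rose to 13 higher and 27 lower without control replicate 3, to 70 and 39 without siCLOCK replicate 1, and to 73 and 43 without the library labelled siCLOCK replicate 3.

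Of 20 measured ATF4 targets and amino acid supply genes, 7 fell in siCLOCK and 13 did not pass, and 16 were lower when adjusted over the list alone. The list median was -0.36 (adjusted p = 2.54e-37, and 0.0396 with an estimated correlation). This call was lost with fry (adjusted p = 0.0516) and with the set term at an estimated correlation (adjusted p = 0.107), although the median with the set term was also -0.36. Of 30 G2/M and mitosis genes none passed over all genes, but 21 were lower when adjusted over the list alone, with a median of -0.17 (list adjusted p = 5.11e-23, and 0.0396 with an estimated correlation). Among these, the phosphatase CDC25C stood at -0.38 (adjusted p = 0.0516), the kinetochore motor CENPE at -0.23, HMMR at -0.30 and the topoisomerase TOP2A at -0.22. None of 26 DNA replication and G1/S genes passed and 1 was lower adjusted over the list alone, the median being -0.10 (list adjusted p = 9.64e-06, adjusted p = 0.559 with an estimated correlation). UHRF1, which maintains DNA methylation, stood at -0.34 (adjusted p = 0.0705). Of 24 matrix and matrix remodelling genes 1 rose (SERPINE2) and 9 were higher adjusted over the list alone (list adjusted p = 3.85e-08, adjusted p = 0.243 with an estimated correlation). The collagenase MMP1 stood at 0.75 and the urokinase gene PLAU at 0.23, neither passing over all genes. None of 18 autophagy and lysosome genes passed (list median 0.09, adjusted p = 0.00295, adjusted p = 0.559 with an estimated correlation). That list call ended without siCLOCK replicate 2 (adjusted p = 0.244). Without the library labelled siCLOCK replicate 3, 10 lists passed in place of 5, and without control replicate 3, 9 passed. With the set term, which in this comparison equals leaving out that siCLOCK library, only the G2/M list passed at an estimated correlation (adjusted p = 0.0223).

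In melatonin against control, most measured cell-cycle genes fell, and the regulators ID2 and ID3 rose. ID2 (ENSG00000115738.9, chromosome 2, 8678845 to 8684453), an inhibitor of basic helix-loop-helix factors, rose from 26.4 CPM ± 0.830 to 64.3 ± 3.32 (SD, n = 3; log2 fold change 1.29, SE 0.07, adjusted p = 8.06e-09), and its relative ID3 from 93.0 CPM ± 10.3 to 229 ± 23.4 (1.30, SE 0.10, adjusted p = 1.44e-07). CYP1A1 (ENSG00000140465.13, chromosome 15, 74719542 to 74725610), a monooxygenase induced by the aryl hydrocarbon receptor (AhR), fell from 7.53 CPM ± 0.556 to 2.34 ± 0.795 (-1.67, SE 0.19, adjusted p = 4.95e-06). CHAC1 (-1.49) and SLC7A11 (-1.24) fell in melatonin as well, as did the amino acid transporter SLC7A5 (-1.17), the matrix protein TGFBI (-1.21), the adhesion receptor ADGRG1 (-1.21), the retinol transporter STRA6 (-1.20) and the scaffold MPP4 (-1.33).

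Further named rises in melatonin were in the histone genes HIST1H2BD (1.11) and HIST1H2AC (0.93), the axonemal dynein DNAH1 (1.07), the secreted glycoprotein OLFM1 (1.04), the nuclear receptor NR4A2 (0.99), the lysosomal sialidase NEU1 (0.98) and the cannabinoid receptor CNR1 (0.92). Some named genes moved with the technical set. EIF3CL, a near-identical copy of EIF3C, was called at 2.56, but it stood at 13.7 CPM in the library labelled siCLOCK replicate 3, and its value with the set term was -0.45 (adjusted p = 0.363). The mitochondrial genes MT-ATP8 (-2.22) and MT-ND6 (-1.50), which overlap or lie antisense to other mitochondrial transcripts in these unstranded counts, went to -0.30 (adjusted p = 0.671) and 0.07 (adjusted p = 0.923) with the set term. CNR1 went to 0.44 (adjusted p = 0.309). The remaining 16 named genes of this comparison passed in the same direction with the set term, ID2 at 1.40, ID3 at 1.65 and CYP1A1 at -1.65. Among them, CHAC1 (-1.99) and SLC7A11 (-1.47) have set-term values that take in how siCLOCK replicates 1 and 2 differed from control (-1.36 and -1.01). For these genes the set-term values are therefore no separate measure of melatonin.

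In all, 1803 genes were higher and 1987 lower in melatonin than in control, among them 1471 and 1813 protein-coding genes. Of 520 processed pseudogenes 168 were higher and 17 lower. With the technical set as a term, chosen after the data were seen, 283 genes were higher and 487 lower, none of the higher ones a processed pseudogene. Of the 3790 calls, 660 were kept in the same direction. The sign was kept by 3605 of these genes, while the median SE rose from 0.101 to 0.170. Calls of higher genes numbered 1201 without control replicate 1, 1082 without control replicate 2, and 1182, 1095 and 1127 without melatonin replicates 1, 2 and 3.

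Of 30 G2/M and mitosis genes, 29 fell in melatonin, NUSAP1 did not pass, and all 30 were lower adjusted over the list alone. The median was -0.72 (list adjusted p = 4.78e-76, and 0.00305 with an estimated correlation). UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 205 CPM ± 6.54 to 103 ± 1.24 (SD, n = 3; -0.99, SE 0.06), the mitotic kinesins KIF20A and KIF23 fell by 0.85 and 0.75 and the kinase AURKA by 0.77 on the log2 scale. Of 26 DNA replication and G1/S genes 24 fell, the cyclin genes CCNE1 and CCNE2 did not pass, and the same number, 24, were lower adjusted over the list alone (median -0.60, list adjusted p = 1.58e-33, and 0.0236 with an estimated correlation, or 0.0974 when the set term is added to the latter, at a median of -0.51). Examples were UHRF1 (-0.88), the transcription factor E2F2 (-0.93), DNA polymerase subunit POLA1 (-0.66) and the replication licensing factor CDT1 (-0.77). With the set term, 28 of the G2/M genes and 17 of the G1/S genes were lower. That fit takes in the fall of siCLOCK replicates 1 and 2 against control (list medians -0.20 and -0.07). The G2/M median relative to the control mean lay between -0.74 and -0.70 in the melatonin libraries, and it was -0.12 in the library labelled siCLOCK replicate 3.

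**Figure D3:**
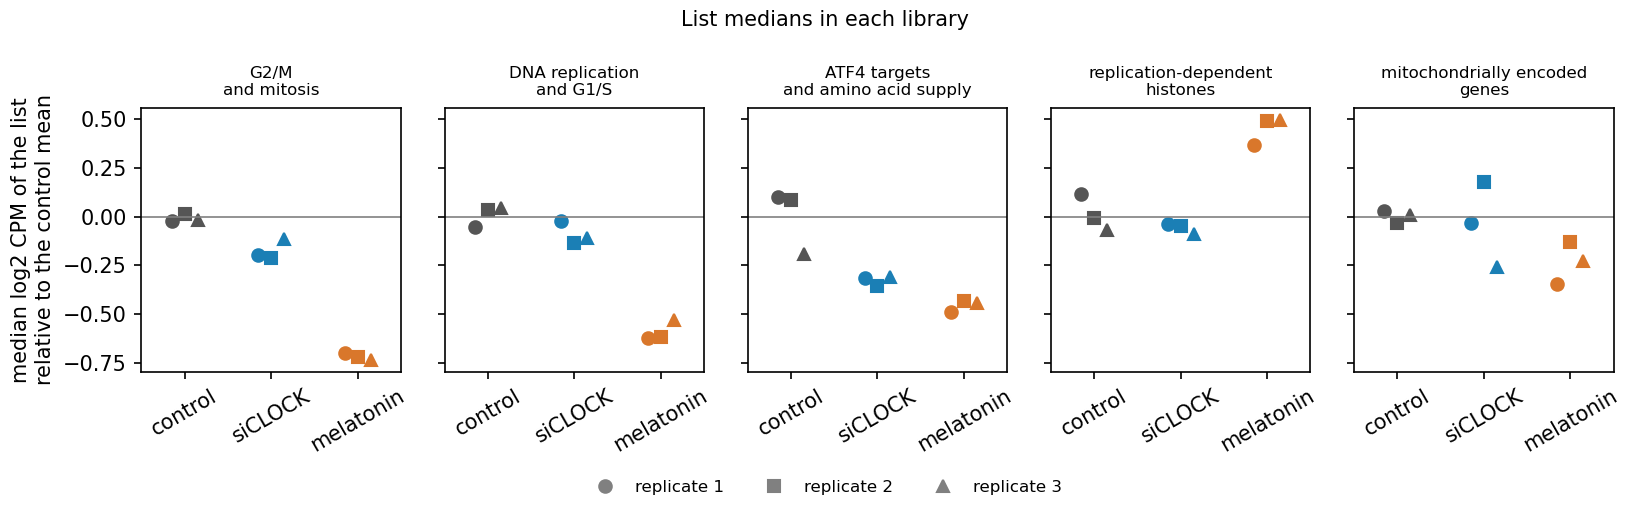
Median log2 CPM of 5 gene lists relative to the control mean (y axis) in each library by group (x axis), with 1 symbol per library and shape for the replicate. The melatonin libraries lie between -0.74 and -0.70 for G2/M and mitosis, whereas for mitochondrially encoded genes the library labelled siCLOCK replicate 3 (-0.26) lies among them.

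Of 20 ATF4 targets and amino acid supply genes, 14 fell in melatonin and 17 were lower adjusted over the list alone (median -0.44, list adjusted p = 3.51e-14, adjusted p = 0.144 with an estimated correlation). The hormone gene STC2 fell by 0.97, PHGDH by 0.70 and MTHFD2 by 0.52 on the log2 scale. With the set term 8 members were lower, but that fit takes in the fall of siCLOCK replicates 1 and 2 against control (list median -0.36). Of 7 measured AhR targets 4 fell and 1 rose, also adjusted over the list alone (median -0.44, list adjusted p = 8.18e-04, adjusted p = 0.0655 with an estimated correlation). Besides CYP1A1 and SLC7A5 these were TIPARP, an AhR-induced ADP-ribosyltransferase (-0.44), and CYP1B1 (-0.47). With the set term 3 members were lower. Of 10 replication-dependent histone genes 6 rose, among them HIST2H2BE (0.62) and HIST1H3H (0.40). Adjusted over the list alone, 7 were higher and 1 lower (median 0.43, list adjusted p = 4.87e-06, adjusted p = 0.0655 with an estimated correlation). Near-identical histone copies share reads, and 4 members were higher with the set term.

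Of 16 unfolded protein response genes 8 rose and 10 were higher adjusted over the list alone (median 0.19, list adjusted p = 3.40e-04, adjusted p = 0.226 with an estimated correlation). Examples were the endoplasmic reticulum chaperone HSPA5 (0.41) and SYVN1 (0.38) and SEL1L (0.31) of protein degradation. Under the set term 2 members were higher, while the median was 0.23 and the list passed (adjusted p = 1.26e-04). Of 18 autophagy and lysosome genes 11 rose, the same number adjusted over the list alone (median 0.23, list adjusted p = 1.78e-05, adjusted p = 0.181 with an estimated correlation). NEU1, the autophagy receptor SQSTM1 (0.51) and the lysosomal membrane protein LAMP2 (0.47) were among them. Under the set term 3 members were higher, while the median was 0.19 and the list passed (adjusted p = 4.19e-05). That fit takes in the rise of siCLOCK replicates 1 and 2 against control (list median 0.10).

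Of 23 hypoxia and glycolysis genes 10 fell and 11 were lower adjusted over the list alone (median -0.21, list adjusted p = 0.00136, adjusted p = 0.445 with an estimated correlation). The glycolytic enzymes PGAM1 (-0.43) and PGK1 (-0.30) and the angiogenic factor VEGFA (-0.48) fell. The list call ended with the set term (adjusted p = 0.0650) and without control replicate 1 (adjusted p = 0.113). Of 25 immediate early genes 3 rose and 10 fell, the same numbers adjusted over the list alone (median -0.16, list adjusted p = 0.00785, adjusted p = 0.444 with an estimated correlation, and 0.994 with the set term). KLF6 (-0.61), the AP-1 subunit FOSL1 (-0.98) and ETV4 (-0.70) fell, and the ERK phosphatase DUSP6 rose by 0.58. Of 14 TGF-beta targets 5 rose and 3 fell, the same numbers adjusted over the list alone. ID1 (0.57), ID2 and ID3, which are also BMP targets, rose and PMEPA1 fell by 0.61 (median 0.02, list higher at adjusted p = 0.0191, adjusted p = 0.301 with an estimated correlation, and 0.0745 without control replicate 3). Of 13 mitochondrially encoded genes 5 fell and 7 were lower adjusted over the list alone (median -0.22, list adjusted p = 0.00106, adjusted p = 0.445 with an estimated correlation). MT-ND2 was called at -0.73 and MT-ND1 at -0.55, but with the set term no member passed and the median was 0.08 (list adjusted p = 0.336).

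**Figure D4:**
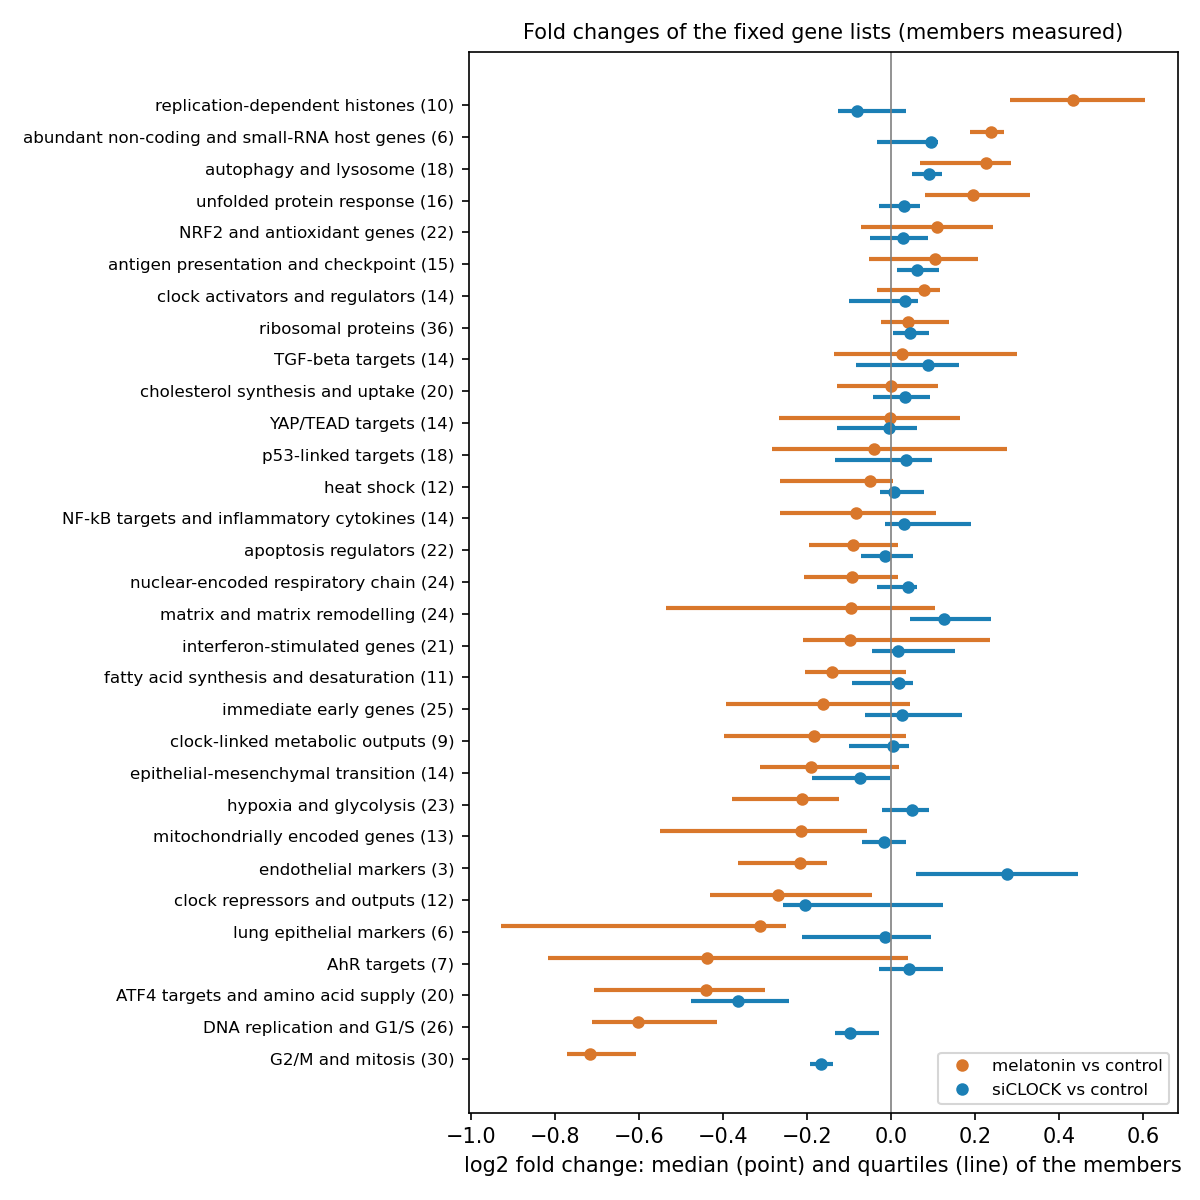
Median (points) and quartiles (lines) of the log2 fold changes of the measured members of each list tested (x axis) for melatonin and siCLOCK against control, with the number of members measured in parentheses. The G2/M list has medians of -0.72 in melatonin and -0.17 in siCLOCK, and the ATF4 list medians of -0.44 and -0.36.

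Clock genes moved in both directions in melatonin against control. Of 12 clock repressors and outputs 4 fell, also adjusted over the list alone: PER3 (-0.46, SE 0.09, adjusted p = 0.00176), BHLHE40, a basic helix-loop-helix repressor (-0.50), the transcription factor DBP (-0.43) and CRY1 (-0.41, adjusted p = 0.0389). Of 14 clock activators and regulators 3 rose, among them NPAS2 (0.47, SE 0.08, adjusted p = 4.66e-04) and the F-box gene BTRC (0.40), and 1 fell, TIMELESS (-0.30), the same numbers adjusted over the list alone. Of 9 clock-linked metabolic outputs 1 rose, PPARA (0.53), and 4 fell, among them the kinase WEE1 (-0.56), while 1 was higher and 5 were lower adjusted over the list alone. NR1D2 stood at 0.02 (adjusted p = 0.949). The lists as wholes did not pass (adjusted p = 0.0938, 0.306 and 0.306). With the set term NPAS2, PPARA and WEE1 passed, and no repressor did. CRY1 went to 0.02, a value that depends on its uneven siCLOCK libraries, and TIMELESS to -0.07 (adjusted p = 0.829). PER3 (-0.42), BHLHE40 (-0.44) and DBP (-0.50) had values of similar size with wider errors. These, and NPAS2 at 0.55, take in how siCLOCK replicates 1 and 2 differed from control: -0.25, -0.20, -0.29 and 0.41. They are therefore no separate measure of melatonin. Against the library labelled siCLOCK replicate 3 alone, melatonin differed by -0.17 for PER3, -0.23 for BHLHE40, -0.22 for DBP and 0.14 for NPAS2. WEE1 differed from that library by -0.57 and PPARA by 0.38. Calls ended without 1 library for CRY1 (any of the 3 control or 3 melatonin libraries), BHLHE40 (control replicate 1), DBP (control replicate 1 or melatonin replicate 1) and TIMELESS (control replicate 2 or melatonin replicate 2).

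Melatonin against siCLOCK asks how the 2 treatments differ. ID2 (1.16, SE 0.07, adjusted p = 4.50e-08) and ID3 (1.03) were higher in melatonin, with HIST1H2BD (1.11), HIST1H2AC (0.997) and OLFM1 (0.83). CYP1A1 (-1.71), ADGRG1 (-1.59, SE 0.11, adjusted p = 1.07e-07), MPP4 (-1.36) and CALB2, a calcium-binding protein gene (-1.21), were lower. ADGRG1 averaged 20.4 CPM ± 1.93 (SD, n = 3) in siCLOCK and 6.78 ± 0.526 in melatonin, and CALB2 157 CPM ± 24.2 and 67.6 ± 3.57. MT-ATP8 was called at -1.71 and went to -0.19 (adjusted p = 0.766) with the set term, while the other 9 named genes passed with it. In all 1221 genes were higher and 1655 lower in melatonin than in siCLOCK. With the set term 328 were higher and 633 lower, and 853 of the 2876 calls were kept in the same direction. Calls numbered 651 higher and 1030 lower without melatonin replicate 1, 628 and 1018 without replicate 2, and 676 and 1037 without replicate 3.

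Against siCLOCK, 29 of 30 G2/M genes were lower in melatonin, the same number adjusted over the list alone (median -0.54, list adjusted p = 1.67e-52, and 0.00878 with an estimated correlation), with UBE2C at -0.81 and the kinase PLK1 at -0.64. Of 26 G1/S genes 24 were lower and 25 adjusted over the list alone (median -0.49, list adjusted p = 7.93e-28, and 0.0337 with an estimated correlation, or 0.0552 with the set term as well, at a median of -0.46), among them the replicative helicase subunits MCM4 (-0.53) and MCM5 (-0.76). Of 10 histone genes 6 were higher, the same number adjusted over the list alone (median 0.55, list adjusted p = 1.69e-09, and 0.0337 with an estimated correlation, or 0.0552 with the set term as well, at a median of 0.51). Of 7 AhR targets 4 were lower, also adjusted over the list alone (median -0.58, list adjusted p = 1.80e-04, and 0.0428 with an estimated correlation, or 0.0552 with the set term as well, at a median of -0.64), among them TIPARP (-0.61) and CYP1B1 (-0.58). Of 24 matrix genes 12 were lower, including LAMB3 (-0.79), ITGA5 (-0.48) and TGFBI (-0.92), and 13 adjusted over the list alone (list adjusted p = 5.31e-07, adjusted p = 0.206 with an estimated correlation).

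Other list calls against siCLOCK were lost with an estimated correlation. Of 23 hypoxia and glycolysis genes 10 were lower, such as PDK1 (-0.51) and LDHA (-0.27), and 14 adjusted over the list alone (list adjusted p = 2.16e-05, adjusted p = 0.357 with an estimated correlation). Of 16 unfolded protein response genes 6 were higher, such as HSPA5 (0.35), and 10 adjusted over the list alone (list adjusted p = 1.80e-04, adjusted p = 0.231 with an estimated correlation). Of 18 autophagy and lysosome genes 6 were higher, such as NEU1 (0.69), while 6 were higher and 1 lower adjusted over the list alone (list adjusted p = 0.00215, adjusted p = 0.357 with an estimated correlation). Of 25 immediate early genes 8 were lower, such as FOSL1 (-1.12) and PHLDA1 (-0.46), and 1 higher, against 10 and 1 adjusted over the list alone (list adjusted p = 6.10e-04, adjusted p = 0.357 with an estimated correlation, and 0.177 with the set term). Mitochondrially encoded genes (5 of 13 lower, 7 over the list alone, list adjusted p = 0.00105), the nuclear-encoded respiratory chain (4 of 24 lower, also over the list alone, such as SDHA at -0.27, list adjusted p = 0.0244) and heat shock genes (4 of 12 lower, such as HSP90AA1 at -0.32, with 1 higher and 5 lower over the list alone, list adjusted p = 0.0269) had adjusted p = 0.482, 0.554 and 0.482 with an estimated correlation, and 0.958, 0.880 and 0.177 with the set term. The respiratory chain call also ended without siCLOCK replicate 1 (adjusted p = 0.181), siCLOCK replicate 2 (0.0548) or melatonin replicate 1 (0.0559), the heat shock call without siCLOCK replicate 1 (0.137), and the mitochondrial call without siCLOCK replicate 2 (0.0775). Of 20 ATF4 targets 3 were lower, the same number adjusted over the list alone, and the list did not pass (median -0.13, adjusted p = 0.0915).

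The last comparison asked which genes both treatments moved. All 11 genes lower in siCLOCK were also lower in melatonin, and 1 of the 9 higher genes, SERPINE2 (0.45 in siCLOCK and 0.46 in melatonin), was also higher in melatonin. Among protein-coding genes with a mean of at least 5 CPM, CHAC1, SLC7A11, ADM2, TRIB3 and GADD45B led the shared falls, with melatonin values of -1.49, -1.24, -0.97, -0.74 and -0.60. SH3TC2-DT (0.68 and -0.48) and LIF (0.40 and -0.37) were higher in siCLOCK and lower in melatonin. In the model with the set term, the melatonin calls of GADD45B (-0.55), SESN2 (-0.51), NXPH4 (-0.52), TRIB3 (-0.48), LIF (-0.18) and SH3TC2-DT (-0.23) ended. That of SH3TC2-DT ended also without control replicate 2 (adjusted p = 0.0724) or melatonin replicate 2 (adjusted p = 0.0638). These set-term values take in how siCLOCK replicates 1 and 2 differed from control. For genes chosen by their siCLOCK calls they are therefore no separate measure of melatonin. Against the library labelled siCLOCK replicate 3 alone, melatonin differed by 0.005 for GADD45B, -0.005 for SESN2, 0.05 for TRIB3 and 0.50 for NXPH4. CHAC1 (-0.68), SLC7A11 (-0.45), LIF (-0.64) and SH3TC2-DT (-0.98) were lower in melatonin than in that library, which is 1 library. Against all 3 siCLOCK libraries, LIF (adjusted p = 2.94e-06) and SH3TC2-DT (adjusted p = 3.66e-06) passed in the F test. CHAC1 (-0.35, adjusted p = 0.26) and SLC7A11 (-0.30, adjusted p = 0.12) did not. The treatments share their 3 control libraries, which alone makes fold changes covary. Across genes, which are not independent replicates, the covariance of the fold changes was 0.0459 against 0.0185 in 20 simulations with no effect of either treatment, and the correlation 0.534 against 0.497. The simulations left out the technical set that the library labelled siCLOCK replicate 3 shares with the melatonin libraries. Its difference from siCLOCK replicates 1 and 2 correlated with melatonin minus control at 0.353 over all genes and 0.759 over processed pseudogenes. The excess covariance therefore cannot be assigned to the treatments. The share of genes with the same sign was lower than simulated, 64.6% against 66.6%. The number of shared genes was 1 without control replicate 1 or without siCLOCK replicate 2, 2 without control replicate 2, 6 and 5 without melatonin replicates 2 and 3, 30 without control replicate 3, 82 without siCLOCK replicate 1 and 61 without the library labelled siCLOCK replicate 3.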

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

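All tests that weigh explanations below were chosen after the results were seen; the counts over other splits of the libraries were planned before.

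The shares of reads that were not counted to genes, which no comparison used, exceeded the highest control library in some treated libraries. For unmapped reads the share was 2.24% in the library labelled siCLOCK replicate 3 and 2.32%, 2.34% and 2.30% in melatonin replicates 1, 2 and 3, against 1.36% in the highest control. For reads at several positions it was 3.83% in siCLOCK replicate 2, 3.75% in the library labelled siCLOCK replicate 3 and 3.77% in melatonin replicates 2 and 3, against 3.70%. For reads outside annotated genes it was 5.89% in the library labelled siCLOCK replicate 3 and 5.58%, 5.63% and 5.60% in the melatonin libraries, against 5.48%. For reads in overlapping genes it was 10.6% in siCLOCK replicate 1, against 10.5%. Groups of 3 libraries are too small for a test of single outlying libraries.

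The first pattern is the rise of 139 processed pseudogenes by at least 2-fold in melatonin. Melatonin itself is argued against as the cause, because 97.1% of them also stood higher in the library labelled siCLOCK replicate 3 than in each of the 5 libraries of the first set. A melatonin library wrongly labelled as siCLOCK replicate 3 is argued against by its G2/M median of -0.116 relative to control, where the highest melatonin library had -0.703. A library or sequencing batch shared by the 4 libraries may be the source: between the library labelled siCLOCK replicate 3 and siCLOCK replicates 1 and 2 these genes differed by a median of 1.32 (log2), close to their melatonin median of 1.59. The labels give no batch, so this stays a hypothesis.

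The second pattern is the fall of cell-cycle genes in melatonin. With the set term 28 G2/M members stayed lower and 0 processed pseudogenes stayed higher. That fit takes in the fall of siCLOCK replicates 1 and 2 against control (list median -0.20), so the count of 28 does not measure melatonin alone. The shared batch is argued against as the whole cause only by the difference within the second technical set, given below, which rests on 1 siCLOCK library. A few genes taking most of the counts are argued against by a largest difference of 1.22 percentage points in the share of the 10 most counted genes. Melatonin itself remains a candidate explanation, as the G2/M median was -0.598 against the library labelled siCLOCK replicate 3 of the same technical set, which is 1 library. Batch effects specific to the melatonin libraries were not tested.

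The third pattern is the fall of ATF4 targets in both treatments against the same controls. For siCLOCK the shared batch is argued against, since replicates 1 and 2, which lie in the set of the controls, had list medians of -0.317 or lower. The lowest control stood at -0.191. For melatonin this test cannot decide, because no melatonin library lies in the set of the controls. The library labelled siCLOCK replicate 3, in the set of the melatonin libraries, stood at -0.312, and the melatonin libraries between -0.491 and -0.432. A single odd control is argued against, because the siCLOCK median stayed between -0.442 and -0.282 when each control was left out. All 3 controls standing high cannot be told apart from an effect of both treatments, as there are only 3 controls and no second control group, and the median of melatonin against siCLOCK was -0.128. The labels describe no non-targeting siRNA control, so the fall in siCLOCK cannot be assigned to the loss of CLOCK.

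For each comparison, 1 of the 10 splits of the 6 libraries, the real one, gave as many calls. The real splits gave 20, 3790 and 2876 genes for siCLOCK against control, melatonin against control and melatonin against siCLOCK, and the highest other split gave 0 in each. Every other split mixes both groups on each side, so any difference between groups or technical sets widens the spread within the sides. Counts near 0 in those splits therefore carry little weight. The 10 splits are too few for a share under 0.05.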

How the results depend on the processing

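The set term and the melatonin comparison without the library labelled siCLOCK replicate 3 were chosen after seeing the data. Counts not named stayed within 1.5 times, and named genes not listed kept their sign, though some lost or gained a call; unless a cause is given, the cause was not tested. For siCLOCK against control (9 higher, 11 lower), the counts were 47 and 29 with DESeq2, 152 and 59 without a filter, 3 and 2 with the strict filter, 3 and 4 with the 6 libraries compared, 73 and 43 with the set term, and 2 and 1 at an adjusted p under 0.01. There were 4 higher with the replicate block, 3 lower with the strand column, and 0 higher and 3 lower at an absolute log2 fold change of at least 1. CLOCK in siCLOCK passed at -0.42 without a filter and -0.62 with the set term, which in this comparison equals leaving out the library labelled siCLOCK replicate 3. For melatonin against control the counts were 283 and 487 with the set term, whose median SE rose from 0.101 to 0.170, 863 and 1137 at 0.01, and 229 and 107 at the fold threshold. For melatonin against siCLOCK they were 328 and 633, 464 and 873, and 86 and 89. Shared genes (12) numbered 45 with DESeq2, 147 without a filter, 3 with the strict filter, 5 with the 6 libraries, 19 with protein-coding genes, 4 with the strand column, 51 with the set term, 2 at the fold threshold and 2 at 0.01. Lists called were 2 of 5, 2 of 11 and 4 of 12 with an estimated correlation for siCLOCK, melatonin and melatonin against siCLOCK. With fry they were 1 and 19 for the first pair, and with the set term 10 for siCLOCK.

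With each library left out, CLOCK in siCLOCK ranged from -0.62 to -0.21, siCLOCK calls from 1 to 73 higher and 1 to 43 lower, melatonin calls from 1082 to 2146 and 1347 to 2353, melatonin against siCLOCK from 628 to 1713 and 1018 to 2147, shared genes from 1 to 82, and lists from 5 to 10, 10 to 14 and 10 to 13. Values that changed sign were HAS3 in siCLOCK (-0.012 with the strand column), CRY1 in siCLOCK (-0.079 without siCLOCK replicate 1, range to 0.32) and, for melatonin with the set term, EIF3CL (-0.45), MT-ND6 (0.071), MT-ND1 (0.081), CRY1 (0.023), NR1D2 (-0.66) and EEF1A1P5 (-0.050). For NR1D2 the set term rests on the library labelled siCLOCK replicate 3, which lacks most of the fall of replicates 1 and 2, so that value is no measure of melatonin. With each library left out, CLOCK in melatonin ranged from -0.042 to 0.062 and NR1D2 from -0.012 to 0.073. Of 111 named genes in melatonin against control, 54 kept their call or its absence with the set term, 51 lost their call and 6 changed sign. Libraries with the same replicate number were no more alike than others, so no pairing by number was seen. With 3 libraries per group this does not exclude a pairing.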

Other observations

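The only test here chosen after the results were seen is the one with the set term. In the lists that did not pass in melatonin against control, single members passed, where 3790 of all 16441 genes did. Of 22 NRF2 and antioxidant genes 6 rose, the same number adjusted over the list alone, among them the ferritin light chain FTL (0.57; list adjusted p = 0.101). Of 15 antigen presentation genes 3 rose, also over the list alone, including B2M (0.45), the light chain of class I molecules (list adjusted p = 0.171). Of 18 p53-linked targets 5 rose, such as TP53INP1 (0.55), and 4 fell, such as the repair gene DDB2 (-0.46), against 5 and 5 adjusted over the list alone (list adjusted p = 0.903, its test pointing up where its median is -0.04). Of 21 interferon-stimulated genes 3 rose, among them IFIT3 (0.74), and OAS3 fell (-0.66), also over the list alone (list adjusted p = 0.791, its test pointing up where its median is -0.10). Of 24 matrix genes 2 rose and 9 fell, also over the list alone, with LAMB3 at -0.73 (list adjusted p = 0.0938), and of 14 epithelial-mesenchymal transition genes 3 fell, also over the list alone, with the tight junction gene CLDN1 at -0.54 (list adjusted p = 0.106). Of 11 fatty acid synthesis genes 1 rose and 3 fell, such as the lipogenic regulator SREBF1 (-0.56), against 2 and 6 adjusted over the list alone (list adjusted p = 0.142), and of 20 cholesterol genes 1 rose and 2 fell, against 0 and 2 (list adjusted p = 0.677).

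In the remaining lists for melatonin against control, none passing as a whole, calls are given over all genes, with those adjusted over the list alone where they differ. NF-kB targets had 1 higher and 1 lower of 14 (LIF at -0.37), YAP/TEAD targets 2 and 3 of 14 (2 and 4 over the list alone; AXL at -0.38), apoptosis regulators 1 and 2 of 22 (1 and 1; CYCS at -0.35) and heat shock genes 0 and 4 of 12 (HSP90AA1 at -0.31), with list adjusted p of 0.552, 0.648, 0.413 and 0.106. The nuclear-encoded respiratory chain had 7 of 24 lower (7 lower and 1 higher over the list alone; ATP5F1B at -0.33), ribosomal proteins 3 higher and 1 lower of 36 (2 and 1; RPL23 at 0.47) and abundant non-coding RNAs 4 higher and 1 lower of 6 (NEAT1 at 0.52), with list adjusted p of 0.106, 0.142 and 0.136. With the set term the ribosomal protein list was higher (median 0.23, adjusted p = 2.30e-08, adjusted p = 0.367 with an estimated correlation).

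The melatonin receptor genes were near the limit of detection, with 0 to 4 counts per library for MTNR1A, 0 to 1 for MTNR1B and 0 to 2 for GPR50. Of the 10 genes of melatonin receptors, synthesis and metabolism 2 were measured and none passed, with NQO2, a quinone reductase that binds melatonin, at 0.05 (adjusted p = 0.578).

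Markers of leukocytes, fibroblasts, endothelium and erythroid cells were low, at most 6.85 CPM in any library, while lung epithelial markers reached 332 CPM. Of the leukocyte markers only ITGAM was measured, and it was lower in melatonin (-1.01, adjusted p = 2.34e-04). Of the fibroblast markers 2 were measured, none over 2.37 CPM, and COL1A1 was lower in melatonin (-0.96, adjusted p = 0.00437). None of 3 measured endothelial markers passed (list adjusted p = 0.648), no erythroid marker was measured and none exceeded 0.274 CPM, and of 6 lung epithelial markers 3 fell in melatonin, such as the keratin KRT8 (-0.31; 4 over the list alone; list adjusted p = 0.118). In siCLOCK no list other than the 5 described passed, and among the members of the lists that did not pass only LIF passed over all genes.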
